A study of Mus musculus with 72 samples.

How the data were processed

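RNA-seq was measured in 52 samples of mouse OT-I CD8+ T cells in 13 groups of 4, and CUT&RUN in 20 samples at 48 h, giving 72 samples. Cells were isolated as splenocytes with red cells lysed, per the labels' protocols. Each RNA group has replicates A to D in the labels. One vehicle group stands for both solvents that the labels' protocols name, DMSO and PBS, so every treatment was compared with the same vehicle libraries.

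The deposited expression table held whole-number counts per gene, made by the authors with featureCounts 2.0.1 over exons in paired mode on the GENCODE M25 annotation (mm10), per the file headers. No strand option was used in that command, per the file headers, although the labels' protocols describe stranded libraries, so reads of a gene and of an overlapping or antisense gene cannot be told apart. The alignments counted had been filtered by the authors, and genes of the mitochondrial genome had 0 counts in every library. FastQC, Bowtie2, STAR, MACS2 and deepTools are named in the submitters' processing notes without a version. The deposited peak lists, 1 for each treatment and mark, gave merged peaks of 2 replicates kept at an IDR of 0.05, with the authors' signal, score and −log10 p or q columns in the IDR layout. These values belong to each peak within its list and were used only to filter or describe it.

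The table held 55487 genes, of which 55141 had a symbol in the reference names and 213 shared a symbol with another identifier. Libraries held 25.6 to 51 M counts. Genes with low counts were filtered by group, TMM factors were computed, and edgeR 4.0.16 quasi-likelihood tests with robust dispersion and Benjamini-Hochberg adjustment at 0.05 were run in R 4.3.3. The 16 libraries of a time shared 1 fit of group means, and unstimulated cells were fitted with the vehicle libraries of the 3 times. The genes tested were 18274 at 4 h, 16269 at 24 h, 16173 at 48 h and 18317 for activation. The common biological coefficient of variation was 0.173, 0.084, 0.093 and 0.132 in these fits. Replicates differed by more than sampling noise and none was merged.

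Gene lists were 32 in number with 636 entries, all found in the table, written before the data were examined: amino acid response, glutamine use, purine, pyrimidine, serine and one-carbon, hexosamine, glycolysis, TCA cycle, nuclear oxidative phosphorylation, mitochondrially encoded, cholesterol, ribosome biogenesis and MYC targets, DNA replication and mitosis, p53 targets, apoptosis, ER unfolded protein response, NRF2 targets, hypoxia, cytotoxic granules, cytokines and chemokines, T cell activation, naive and memory, inhibitory receptors and TOX, effector differentiation, interferon, H3K27 enzymes, and markers of CD8 T, CD4 T, B, NK, myeloid and erythroid cells. Lists of at least 3 tested members were compared with other genes by camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over lists within a comparison. Estimated correlations and fry were run beside it. With an estimated correlation 29 of the 255 calls of the gene list tests held.

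Genes named in the report were chosen by a rule fixed before the data were examined. A candidate had a symbol that is not a predicted gene, clone or receptor segment, an adjusted p under 0.05, a mean log2 CPM of at least 3 and CPM of the groups not overlapping. The largest log2 fold changes were taken: 6 up and 6 down for treatment against vehicle at 24 h and 48 h, 4 and 4 at 4 h and for activation, and 4 and 4, or 2 and 2 at 4 h, between treatments. Up to 4 members of each described list with the smallest adjusted p and a fixed panel of metabolic, effector and receptor genes were added. Some genes that this rule chose are not reported here. Folds against groups with 0 counts were computed against a floor of 3 counts over the group. Such floors cover counting error only, whereas SEs and the interval for Cd4 come from fits with a dispersion.

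Replicate letters were checked for pairing by the correlation of deviations from group means between samples of the same letter. Every pair exceeded 0.1 for CB-839 against vehicle at 4 h (r = 0.57 to 0.67) and 24 h (0.59 to 0.76), DON against vehicle at 4 h (0.21 to 0.66), glutamine-free medium against DON at 24 h (0.12 to 0.36) and DON against CB-839 at 48 h (0.17 to 0.31). The labels do not say what a letter shares. The unblocked fit is the one reported, with the block as an alternative.

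Overlaps between treatments sharing vehicle libraries were set against 10 simulations of unchanged groups and against 6 splits of the vehicle libraries. Peaks were compared by an overlap of at least 1 base, and promoters were taken as 1000 bases either side of the annotated start. Alternatives were RLE scaling, library totals only, no count filter, DESeq2 1.42.0, the replicate block, a fit of all 52 libraries, a fit of the 8 libraries compared, leaving out each library, stricter IDR, 50% overlap, covered bases and a window of 2500 bases. The block together with the 8 libraries, and IDR 0.03 and 0.02, were added after seeing the data.

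The count test was tested on simulated data drawn from the real means with 50 genes changed at each of 4 sizes. For CB-839 against vehicle at 24 h, 34%, 70%, 64% and 92% of genes changed by 1.25, 1.5, 2 and 4-fold were recovered. These were among 15341 genes, with 7 false calls of 137. At 4 h 18%, 32%, 52% and 82% were recovered among 17098 genes, with 5 false calls of 97. The IgG samples have no file used here. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.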

Results

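CD8+ T cells from OT-I mice, whose T cell receptor recognises the ovalbumin peptide SIINFEKL, were activated in splenocyte cultures with the peptide at 10 ng/mL and IL-2 at 100 IU/mL. The series asks how glutamine metabolism shapes the activated cell. Glutamine is a nitrogen and carbon donor for nucleotide, amino sugar and amino acid synthesis. Cultures received vehicle, CB-839 at 1 µM (a small-molecule inhibitor of glutaminase), DON at 1 µM (a glutamine analog that inhibits enzymes using glutamine) or medium without glutamine. RNA-seq covered unstimulated cells and each of the 4 conditions at 4 h, 24 h and 48 h, with 4 libraries in each of 13 groups. The 52 libraries held 25.6 to 51 M assigned counts, and 22061 to 32295 genes had a count in a library. Group means of the library total lay between 36.1 ± 4.18 M (SD, DON at 4 h) and 45.8 ± 3.95 M (SD, CB-839 at 24 h). CUT&RUN, which maps a histone mark by antibody-targeted cleavage of chromatin, covered H3K27ac and H3K27me3 at 48 h with 2 samples per condition and mark, and IgG with 1 sample per condition.

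Gene values below are log2 fold changes ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, or CPM (count scaled to library size) as mean ± SD, with n = 4 libraries per group. Gene lists were compared with the other genes by limma's camera at a preset correlation, with a repeat at an estimated correlation. The labels do not say whether the 4 libraries of a group came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

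**Figure D1:**
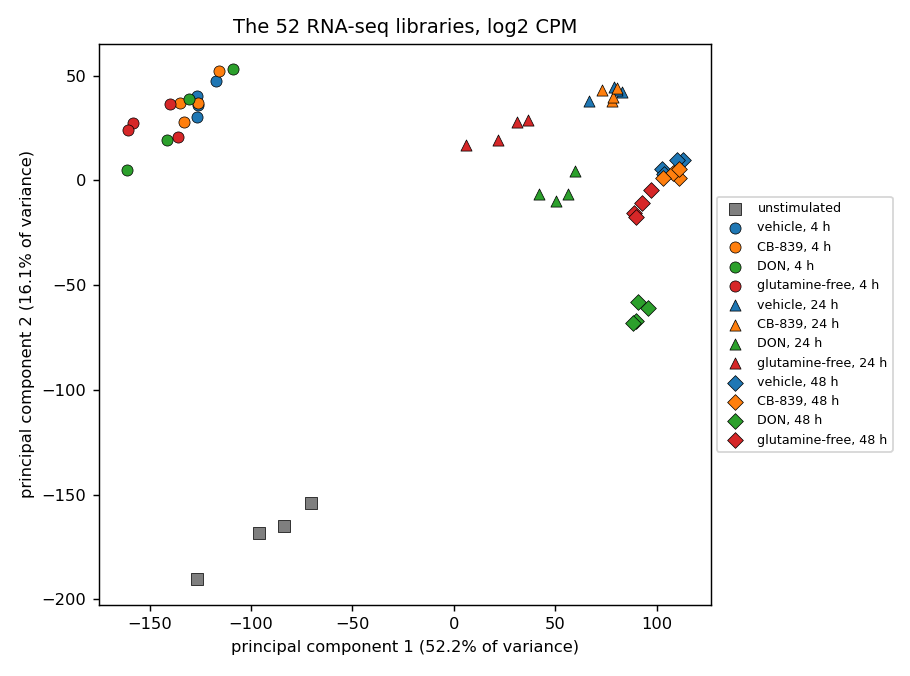
Principal components of log2 CPM for the 52 RNA-seq libraries, with PC1 (52.2% of the variance) on the horizontal axis and PC2 (16.1%) on the vertical axis, each point being 1 library, colour marking the treatment and shape the time. Time after stimulation set the main separation, and the 4 unstimulated libraries lay together.

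Stimulation without inhibition was followed against unstimulated cells. By 4 h the chemokine gene Xcl1 had risen from 0.994 ± 0.0689 to 3740 ± 383 CPM (log2 fold change 11.87 ± 0.16, edgeR adjusted p = 1.72e-20), Il2 rose by 10.52 ± 0.23 and Ccl3 by 10.32 ± 0.20. Il3 had 0 counts in the 4 unstimulated libraries and was at least 3480-fold higher at 4 h against a floor of 3 counts over the group. The steepest falls at 4 h among genes with a mean log2 CPM of at least 3 that met the naming rule were Ampd1 (−6.93 ± 0.17), Dusp10 (−6.78), Nsg2 (−6.59) and Dtx1 (−6.48). At 24 h Batf3, an AP-1 family factor, was up by 10.16 ± 0.39, Crabp2 by 10.18 and Cth by 9.91, while Cd7 fell by 10.26 ± 0.17, Klf2 fell by 8.25 ± 0.19, Baiap3 fell by 8.16 and Lcn4 fell by 7.76. At 48 h Batf3 (12.26 ± 0.38), Il2ra (9.28 ± 0.14) and Zbtb32 (9.11 ± 0.16) were among the large rises, and Cd7 (−10.74 ± 0.18), Ccr9 (−9.41 ± 0.18), Car1 (−8.85) and Ifi213 (−8.69) fell. Ifng, encoding interferon gamma, was higher by 7.96 ± 0.31 at 4 h and 7.65 ± 0.31 at 24 h but by 2.86 ± 0.27 at 48 h. Gzmb, encoding granzyme B, reached 4920 ± 602 CPM at 24 h from 14.4 ± 3.47 CPM.

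Of the 25 T cell activation genes tested at 4 h, 23 rose and 1 fell (also 23 and 1 adjusted over the list alone, camera adjusted p = 2.62e-10, adjusted p = 0.00666 with an estimated correlation), including Tnfrsf9 (8.76), Il2ra (8.63) and Egr2 (5.33). Cytokines and chemokines rose in 17 of 20 and fell in 3 (17 and 3 adjusted over the list alone, camera adjusted p = 9.48e-06, adjusted p = 0.199 with an estimated correlation). Every one of the 32 genes of ribosome biogenesis and MYC targets rose at each of the 3 times (32 adjusted over the list alone), with adjusted p = 0.119, 0.131 and 0.116 with an estimated correlation at 4 h, 24 h and 48 h. The 41 genes of DNA replication and mitosis all rose at 24 h and at 48 h, with a median of 4.02 at both times (41 adjusted over the list alone, adjusted p = 0.131 and 0.116 with an estimated correlation). Naive and memory genes, which include the homing receptor S1pr1 (−6.44) and Tcf7 (−5.22), fell in 18, 19 and 22 of 24 at the 3 times (18, 19 and 22 adjusted over the list alone, adjusted p = 0.223, 0.131 and 0.116 with an estimated correlation). At 48 h interferon-stimulated genes were lower in 22 of 26 and higher in 4 (22 and 4 adjusted over the list alone, camera adjusted p = 0.00285, adjusted p = 0.59 with an estimated correlation), among them Irf7 (−5.52) and Ddx58 (−3.93). The share of counts in B cell markers was 0.1669% ± 0.0112 (SD) in unstimulated cells and 0.2235% ± 0.0132 (SD), 0.0413% ± 0.0007 (SD) and 0.0531% ± 0.0025 (SD) with vehicle at the 3 times. The counts of changed genes were 13722 (6210 up, 7512 down) at 4 h, 15422 (7084 up, 8338 down) at 24 h and 15277 (7022 up, 8255 down) at 48 h. With no low-count filter 13537 genes fell at 24 h and 13259 at 48 h. The median log2 fold change of all genes tested was −0.21, −0.176 and −0.163 with TMM scaling, against which the changes are read, and −0.447, −0.476 and −0.439 with library totals alone.

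CB-839 against vehicle addressed the loss of glutaminase activity. At 4 h it raised Dnajb13 from 4.29 ± 0.547 to 12.1 ± 1.52 CPM (1.49 ± 0.12, edgeR adjusted p = 5.6e-07), the lipase gene Lipg (0.96 ± 0.06), Dop1b (0.96 ± 0.08) and Col11a2 (0.92 ± 0.09). The granzyme gene Gzmc fell from 28 ± 3.71 to 11 CPM (−1.35 ± 0.15, edgeR adjusted p = 2.13e-05), beside Nipsnap2 (−1.08 ± 0.07), Rnf157 (−1.05 ± 0.13) and Zswim7 (−0.99 ± 0.11). Ifng was lower by −0.70 ± 0.16 and Il2 by −0.45 ± 0.11, Cd8a was higher by 0.55 ± 0.07, and Gzmb (−0.38 ± 0.16, edgeR adjusted p = 0.176) did not pass. Gzmb passed in a fit of the 8 libraries compared, with and without the replicate block, and not with the block in the shared fit. In all 2282 genes changed, 1069 up and 1213 down, of which 23 and 26 changed by at least 2-fold.

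The amino acid response list, ATF4 targets induced when amino acids run short, was lower at 4 h: 14 of 35 members fell and 2 rose (20 and 2 adjusted over the list alone, camera adjusted p = 3.96e-08, adjusted p = 0.707 with an estimated correlation), including Pck2 (−0.81 ± 0.09), Mars (−0.54 ± 0.06) and Asns (−0.39 ± 0.06). The block among the 8 libraries compared gave 22 down. Of nuclear genes of oxidative phosphorylation 11 of 40 fell and 0 rose (12 and 0 adjusted over the list alone, camera adjusted p = 3.96e-08, adjusted p = 0.707 with an estimated correlation). TCA cycle genes fell in 8 of 21 (10 down and 1 up adjusted over the list alone, camera adjusted p = 0.000269, adjusted p = 0.707 with an estimated correlation). ER chaperone and unfolded protein response genes fell in 7 of 18 and rose in 1 (10 and 2 adjusted over the list alone, camera adjusted p = 0.000855, adjusted p = 0.707 with an estimated correlation). Serine and one-carbon genes fell in 6 of 14 (7 adjusted over the list alone, camera adjusted p = 0.0238, adjusted p = 0.767 with an estimated correlation).

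Apoptosis regulators rose in 5 of 21 at 4 h and fell in 2 (8 and 2 adjusted over the list alone, camera adjusted p = 0.00343, adjusted p = 0.445 with an estimated correlation): Bcl2l11 (0.70 ± 0.05) and Fasl (0.98 ± 0.11) promote cell death, whereas Mcl1 (0.35 ± 0.05) restrains it. Interferon-stimulated genes rose in 4 of 26 (5 adjusted over the list alone, camera adjusted p = 0.000648, adjusted p = 0.767 with an estimated correlation). Ifi47 was at 0.59 ± 0.10 and Gbp2 at 0.59 ± 0.16. Naive and memory genes rose in 4 of 24 (4 adjusted over the list alone, camera adjusted p = 0.0376, adjusted p = 0.767 with an estimated correlation), namely Lef1 (0.77 ± 0.10), Il6ra (0.63 ± 0.07), Cd27 (0.59 ± 0.06) and Tcf7 (0.56 ± 0.13); with the replicate letter as a block this list had adjusted p = 0.0595. B cell markers had a median of 1.11 with 0 of 16 members passing (0 adjusted over the list alone, camera adjusted p = 0.0369, adjusted p = 0.839 with an estimated correlation). Their share of all counts was 0.257% ± 0.043 (SD) with CB-839 and 0.224% ± 0.0132 (SD) with vehicle. The count of 2282 was 1465 with no low-count filter, 1518 in a fit of all 52 libraries and 4899 with the block among the 8 libraries compared.

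After 24 h of CB-839, interferon-inducible genes were among those that rose, with Ifi206 at 1.21 ± 0.12 (edgeR adjusted p = 7.15e-06), Tgtp1 at 1.00 ± 0.12, Iigp1 at 0.98 ± 0.18, Trim34a at 0.90 ± 0.11 and the RNA sensor gene Ifih1 at 0.89 ± 0.09, beside Idi2 (1.10 ± 0.12). Ifng fell from 577 ± 140 to 289 ± 44.8 CPM (−1.0 ± 0.16, edgeR adjusted p = 0.00164). Other falls were Batf3 (−1.14 ± 0.21), the cationic amino acid transporter gene Slc7a3 (−1.09 ± 0.23), Plk2 (−1.05 ± 0.12), Cth (−0.98 ± 0.13) and Zswim7 (−0.88 ± 0.11). Gzmb (−0.07 ± 0.15, edgeR adjusted p = 0.853) and Prf1 (0.12 ± 0.09, edgeR adjusted p = 0.499) did not pass. Prf1 passed only with the replicate block among the 8 libraries compared, and Gzmb did not. Interferon-stimulated genes rose in 14 of 26 and fell in 0 (21 and 0 adjusted over the list alone, camera adjusted p = 6.4e-18, adjusted p = 0.214 with an estimated correlation). Amino acid response genes fell in 13 of 35 and rose in 0 (27 and 0 adjusted over the list alone, camera adjusted p = 2.01e-17, adjusted p = 0.231 with an estimated correlation). Asns, which makes asparagine with nitrogen from glutamine, was at −0.77 ± 0.15 and Chac1 at −0.87 ± 0.19. The number of amino acid response genes that fell was 6, 4 and 24 without vehicle libraries A, B and D. It was 24 by DESeq2, 28 with the replicate letter as a block, 7 in a fit of all 52 libraries, 4 in a fit of the 8 libraries compared and 29 with the block in that fit.

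Further lists were called at 24 h of CB-839 with the preset correlation. Cholesterol synthesis genes fell in 4 of 22 (9 adjusted over the list alone, camera adjusted p = 1.52e-06, adjusted p = 0.231 with an estimated correlation). Serine and one-carbon genes fell in 4 of 14 (7 adjusted over the list alone, camera adjusted p = 0.000789, adjusted p = 0.214 with an estimated correlation). TCA cycle genes fell in 2 of 21 (2 adjusted over the list alone, adjusted p = 0.481 with an estimated correlation). Oxidative phosphorylation genes fell in 1 of 40 (1 adjusted over the list alone, adjusted p = 0.604 with an estimated correlation). Apoptosis regulators rose in 3 of 21 and fell in 1 (4 and 1 adjusted over the list alone, camera adjusted p = 0.0155, adjusted p = 0.214 with an estimated correlation). In all 806 genes changed, 402 up and 404 down, and 34 and 26 by at least 2-fold. The count was 1840 with the replicate block, 1295 by DESeq2, 441 with the 8 libraries compared and 229 with all 52 libraries. It was 485 and 398 without vehicle libraries A and B, and 530, 453 and 520 without CB-839 libraries A, C and D.

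By 48 h of CB-839 Asns (ENSMUSG00000029752.12, mm10 chromosome 6, 7675169 to 7693254) was at 154 ± 20.4 CPM against 77.2 ± 5.56 CPM (1.00 ± 0.09, edgeR adjusted p = 1.25e-06), and Slc6a9 (1.31 ± 0.13), Pck2 (1.3 ± 0.11), Aldh1l2 (1.24 ± 0.18) and Gpt2 (1.24 ± 0.10) were among the rises, with Gbp10 (1.40 ± 0.13) and Iigp1 (1.33 ± 0.15). Among genes with a mean log2 CPM of at least 3 that met the naming rule the largest falls were Ifng (ENSMUSG00000055170.4, chromosome 10, 118441046 to 118445892) at 8.06 ± 2.08 against 21.2 ± 6.20 CPM (−1.39 ± 0.23, edgeR adjusted p = 0.000853), S100a6 (−1.37 ± 0.25), Plk2 (−1.35 ± 0.11), the cell cycle inhibitor gene Cdkn1a (−1.31 ± 0.10, edgeR adjusted p = 3.6e-07), Dennd5a (−1.25 ± 0.08) and Inka2 (−1.22 ± 0.13). Gzmb was at 5390 ± 532 CPM against 5330 ± 673 CPM (0.02 ± 0.12, edgeR adjusted p = 0.957), Lag3 rose by 0.51 ± 0.08 and Il7r fell by 0.62 ± 0.10. Exons of Ifng and Slc6a9 overlap those of another annotated gene over more than 20% of their length, so their counts are uncertain.

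In the amino acid response list 25 of 35 members rose at 48 h and 0 fell (26 and 3 adjusted over the list alone, camera adjusted p = 5.03e-18, adjusted p = 0.0645 with an estimated correlation). The block among the 8 libraries compared gave 9 up. Interferon-stimulated genes rose in 19 of 23 (19 adjusted over the list alone, camera adjusted p = 6.11e-19, adjusted p = 0.000698 with an estimated correlation). Irf7 was at 1.73 ± 0.15, Usp18 at 1.79 ± 0.19 and Xaf1 at 1.40 ± 0.13. Targets of p53 fell in 16 of 22 and rose in 0 (19 and 0 adjusted over the list alone, camera adjusted p = 3.24e-13, adjusted p = 0.0105 with an estimated correlation). Phlda3 was at −1.21 ± 0.14 and Zmat3 at −0.74 ± 0.08. Serine and one-carbon genes rose in 8 of 14 and fell in 1 (8 and 1 adjusted over the list alone, camera adjusted p = 0.00088, adjusted p = 0.166 with an estimated correlation). Glycolysis genes rose in 6 of 20 and fell in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.0243, adjusted p = 0.575 with an estimated correlation). Ribosome biogenesis and MYC targets fell in 6 of 32 and rose in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.00186, adjusted p = 0.508 with an estimated correlation). Pyrimidine and deoxynucleotide genes fell in 4 of 14 (6 down and 1 up adjusted over the list alone, adjusted p = 0.465 with an estimated correlation). Cholesterol genes fell in 2 of 22 (2 adjusted over the list alone, adjusted p = 0.465 with an estimated correlation). In all 2464 genes changed, 1375 up and 1089 down, and 99 and 124 by at least 2-fold. The count was 3694 without vehicle library C, 1523 without CB-839 library A, 1166 in a fit of all 52 libraries, 1054 in a fit of the 8 libraries compared and 331 with the block in that fit.

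DON at the same dose was followed from 4 h, when no single gene passed. The test gave no call in edgeR (0 genes, 1862 at an unadjusted p under 0.05), 27 passed in DESeq2 and 25 in a fit of the 8 libraries compared, rising to 528 there with the replicate letter as a block (0 with the block in the shared fit), while library totals alone gave 8. Asns stood at 20.2 ± 1.10 CPM against 19.4 ± 0.611 CPM (0.06 ± 0.06, edgeR adjusted p = 0.75) and Ifng at 758 ± 101 against 710 ± 104 CPM (0.09 ± 0.15, edgeR adjusted p = 0.887). The T cell activation list lay below the other genes with a median of −0.14, with 0 of 25 members passing and 9 down adjusted over the list alone (camera adjusted p = 2.29e-10, adjusted p = 0.246 with an estimated correlation). Lower too were the amino acid response (median −0.08, 0 of 35 passing and 0 adjusted over the list alone, camera adjusted p = 5.48e-05, adjusted p = 0.972 with an estimated correlation) and enzymes of H3K27 marks (median −0.06, 0 of 18 passing and 4 down adjusted over the list alone, camera adjusted p = 0.00692, adjusted p = 0.847 with an estimated correlation). With the replicate letter as a block, glutamine use genes (camera adjusted p = 0.0391) and naive and memory genes (camera adjusted p = 0.00376) were also called at 4 h, each with 0 members passing in the unblocked fit. CD8 T cell markers were lower too (median −0.08, 0 of 13 passing and 0 adjusted over the list alone, camera adjusted p = 0.0161, adjusted p = 0.972 with an estimated correlation).

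At 24 h of DON 9433 genes differed from vehicle. The nuclear noncoding RNA Neat1 rose from 10.4 ± 0.614 to 143 ± 7.98 CPM (3.78 ± 0.08, edgeR adjusted p = 3.79e-17), Tbc1d4 by 3.22 ± 0.13, Rab26os by 3.2 ± 0.13, Gt(ROSA)26Sor by 2.90 ± 0.11, Mir155hg by 2.56 ± 0.12 and Tspan2 by 2.53 ± 0.11. Among genes with a mean log2 CPM of at least 3 that met the naming rule, replication-dependent histone genes had the largest falls, Hist1h3c from 57.5 ± 14.5 to 3.66 ± 0.843 CPM (−3.99 ± 0.20), Hist1h2bj by 3.95 ± 0.20 and Hist1h2ae by 3.26 ± 0.22, followed by Scd1 (−2.64 ± 0.15), Lipg (−2.55 ± 0.13) and Pif1 (−2.46 ± 0.15). Ifng was at −2.16 ± 0.17 (edgeR adjusted p = 8.36e-09), Gzmb at −1.27 ± 0.16 and the perforin gene Prf1 at −2.18 ± 0.09, whereas Tcf7 (0.54 ± 0.05), Il7r (1.15 ± 0.21) and Cd8a (0.73 ± 0.05) rose. The lists of cytotoxic granule (adjusted p = 0.107 in camera) and effector differentiation genes (adjusted p = 0.206 in camera) were not called. The histone genes belong to a family of near-identical copies, and Rab26os is an antisense gene counted without strand, so these values are uncertain. The B cell share of counts was 0.0622% ± 0.0098 (SD) against 0.0413% ± 0.0007 (SD) with vehicle.

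Of the lists lower at 24 h of DON, T cell activation alone was also called with an estimated correlation. Ribosome biogenesis and MYC targets fell in 31 of 32 (31 adjusted over the list alone, camera adjusted p = 6.04e-13, adjusted p = 0.15 with an estimated correlation). Glycolysis genes fell in 18 of 20 (18 adjusted over the list alone, camera adjusted p = 8.53e-08, adjusted p = 0.224 with an estimated correlation). The glucose transporter gene Slc2a1 was at −1.24 ± 0.09. DNA replication and mitosis genes fell in 31 of 41 with 3 up (31 and 3 adjusted over the list alone, camera adjusted p = 4.54e-09, adjusted p = 0.335 with an estimated correlation). T cell activation genes fell in 17 of 25 and rose in 2 (17 and 2 adjusted over the list alone, camera adjusted p = 0.000261, adjusted p = 0.0294 with an estimated correlation). Tbx21 was at −1.03 ± 0.07 and Egr1 at −1.03 ± 0.10. Of amino acid response genes 29 of 35 fell and 1 rose (29 and 1 adjusted over the list alone, camera adjusted p = 8.53e-08, adjusted p = 0.338 with an estimated correlation), with Atf4 itself at −0.84 ± 0.05 and Slc7a5 at −1.35 ± 0.10. Cholesterol genes fell in 18 of 22 and rose in 1 (18 and 1 adjusted over the list alone, camera adjusted p = 1.03e-05, adjusted p = 0.182 with an estimated correlation). ER unfolded protein response genes fell in 14 of 18 and rose in 1 (14 and 1 adjusted over the list alone, camera adjusted p = 0.000106, adjusted p = 0.0892 with an estimated correlation).

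Further lists were called lower at 24 h of DON with the preset correlation and not with an estimated one. Serine and one-carbon genes fell in 11 of 14 (11 adjusted over the list alone, adjusted p = 0.105 with an estimated correlation). Targets of p53 fell in 13 of 21 with 3 up (14 and 3 adjusted over the list alone, adjusted p = 0.384 with an estimated correlation). NRF2 targets fell in 11 of 18 with 1 up (13 and 1 adjusted over the list alone, adjusted p = 0.15 with an estimated correlation). Glutamine use genes fell in 13 of 21 and rose in 4 (14 and 4 adjusted over the list alone, camera adjusted p = 0.0251, adjusted p = 0.15 with an estimated correlation). Hypoxia response genes fell in 12 of 20 and rose in 5 (12 and 5 adjusted over the list alone, adjusted p = 0.356 with an estimated correlation). Oxidative phosphorylation genes fell in 22 of 40 with 3 up (24 and 3 adjusted over the list alone, adjusted p = 0.45 with an estimated correlation). Pyrimidine genes fell in 9 of 14 with 1 up (9 and 2 adjusted over the list alone, adjusted p = 0.394 with an estimated correlation). The 9433 changed genes were 4567 up and 4866 down, with 1692 and 495 changed by at least 2-fold. Higher genes made up 48.4% of the calls with TMM and 70.5% with library totals alone, which put the median of all genes at 0.185.

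At 48 h of DON the integrin gene Itgae (ENSMUSG00000005947.11, chromosome 11, 73090583 to 73147446) rose from 1.08 ± 0.224 to 37.3 ± 6.48 CPM (5.09 ± 0.17, edgeR adjusted p = 1.01e-14). Mxd4, a MAX partner that opposes MYC, rose by 4.87 ± 0.14, Lgals3 by 4.19 ± 0.14, Aqp3 by 4.18 ± 0.09, Amn1 by 4.04 ± 0.13 and Rab26os by 5.40 ± 0.23. Klf2 was at 64 ± 7.36 against 4.93 ± 0.634 CPM (3.70 ± 0.12), Tcf7 at 1.52 ± 0.06, Il6st at 2.04 ± 0.08 and S1pr1 at 1.65 ± 0.09, while the naive and memory list, with 14 up and 9 down of 24, was not called (adjusted p = 0.129 in camera). Ifng was at 1.52 ± 0.48 against 21.2 ± 6.20 CPM (−3.79 ± 0.28, edgeR adjusted p = 2.67e-09), Gzmb (ENSMUSG00000015437.5, chromosome 14, 56258838 to 56262260) at 820 ± 68.7 against 5330 ± 673 CPM (−2.70 ± 0.13), and Prf1 at −2.82 ± 0.13. The largest falls among genes with a mean log2 CPM of at least 3 that met the naming rule were Chac1 (−4.65 ± 0.31), Scd1 (−4.64 ± 0.17), H1f0 (−3.90 ± 0.09), Nupr1 (−3.86 ± 0.27) and Tnfrsf8 (−3.84 ± 0.18), while Il2 (2.27 ± 0.32) rose from 0.367 ± 0.207 to 1.73 ± 0.34 CPM.

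All 32 genes of ribosome biogenesis and MYC targets fell at 48 h of DON (32 adjusted over the list alone, camera adjusted p = 2.72e-14, adjusted p = 0.0259 with an estimated correlation), and Myc was at −0.66 ± 0.06. Cholesterol genes fell in 21 of 22 (21 down and 1 up adjusted over the list alone, camera adjusted p = 2.67e-09, adjusted p = 0.0139 with an estimated correlation). Sqle was at −2.04 ± 0.05. DNA replication and mitosis genes fell in 32 of 41 and rose in 1 (32 and 1 adjusted over the list alone, camera adjusted p = 3.71e-08, adjusted p = 0.0233 with an estimated correlation). T cell activation genes fell in 19 of 25 and rose in 2 (19 and 2 adjusted over the list alone, camera adjusted p = 6.08e-05, adjusted p = 0.0139 with an estimated correlation): Tbx21 was at −2.65 ± 0.10, Il2ra at −1.87 ± 0.08 and Irf4 at −1.71 ± 0.07, whereas Nr4a2 was at 1.67 ± 0.08. Falls reached 32 of 35 amino acid response genes, and 3 rose (32 and 3 adjusted over the list alone, camera adjusted p = 7.86e-09, adjusted p = 0.12 with an estimated correlation). Atf3 was at −3.21 ± 0.09, Trib3 at −2.95 ± 0.11 and Asns at 27.9 ± 3.44 against 77.2 ± 5.56 CPM (−1.47 ± 0.09). Glycolysis genes fell in 19 of 20 (19 adjusted over the list alone, camera adjusted p = 3.71e-08, adjusted p = 0.0853 with an estimated correlation).

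More lists were called at 48 h of DON with the preset correlation and not with an estimated one. Falls were called in 12 of 14 pyrimidine genes (12 adjusted over the list alone, adjusted p = 0.0786 with an estimated correlation), 10 of 12 purine genes with 1 up (10 and 1 adjusted over the list alone, adjusted p = 0.18 with an estimated correlation), 11 of 14 serine and one-carbon genes (11 adjusted over the list alone, adjusted p = 0.0745 with an estimated correlation) and 14 of 21 glutamine use genes with 4 up (14 and 4 adjusted over the list alone, adjusted p = 0.209 with an estimated correlation). Hypoxia response genes fell in 15 of 19 and rose in 2 (15 and 3 adjusted over the list alone, adjusted p = 0.0942 with an estimated correlation). Egln3 was at −3.01 and Vegfa at −2.54. ER unfolded protein response genes fell in 16 of 18 with 1 up (16 and 1 adjusted over the list alone, adjusted p = 0.0853 with an estimated correlation). NRF2 targets fell in 13 of 19 (13 adjusted over the list alone, adjusted p = 0.0853 with an estimated correlation). B cell markers rose in 8 of 9 and fell in 1 (8 and 1 adjusted over the list alone, camera adjusted p = 0.0118, adjusted p = 0.14 with an estimated correlation), and their share of counts was 0.0802% ± 0.0021 (SD) against 0.0531% ± 0.0025 (SD) with vehicle. The CD4 share was 0.0072% ± 0.0004 (SD) against 0.003% ± 0.0002 (SD). In all 11513 genes changed, 5755 up and 5758 down, with 2739 and 1441 changed by at least 2-fold. Higher genes made up 50% of the calls with TMM and 62.8% with library totals alone, which put the median of all genes at 0.186.

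**Figure D2:**
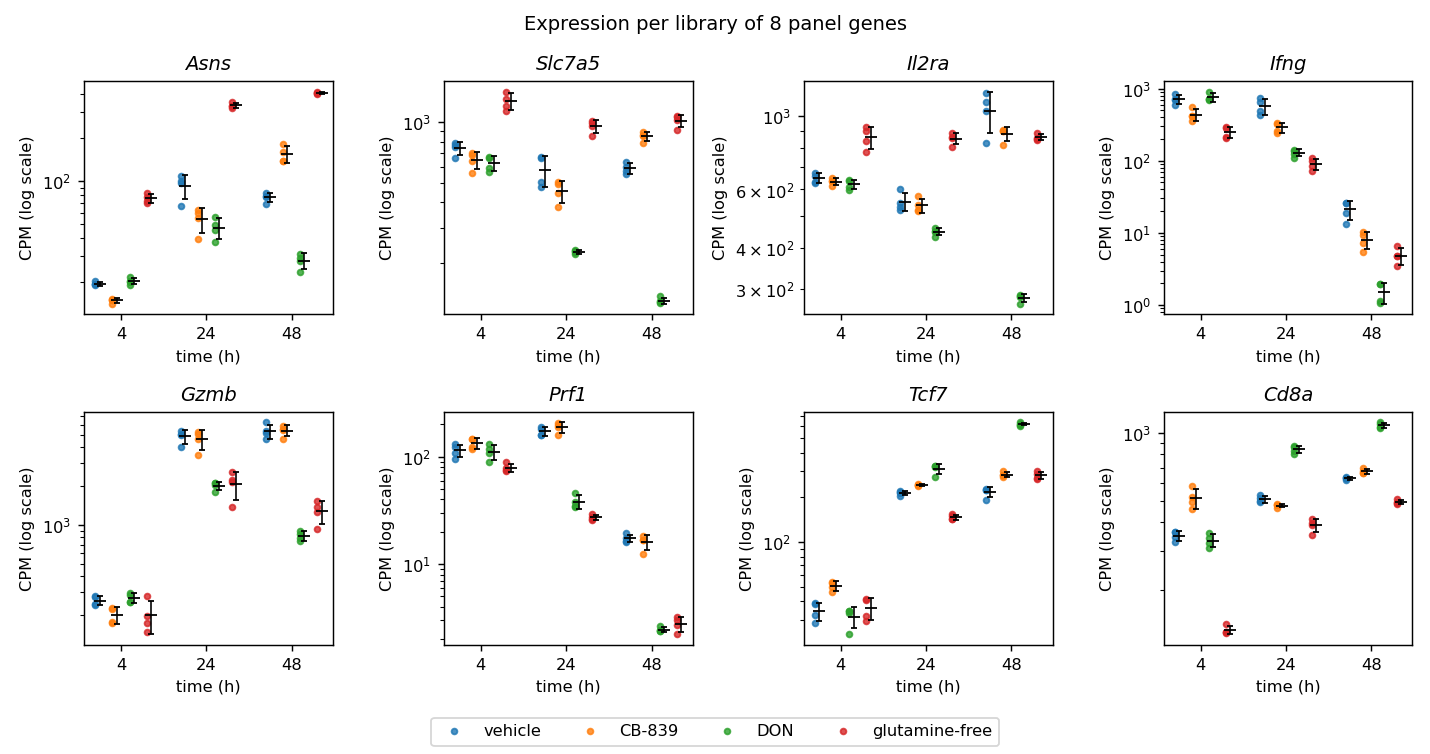
CPM on a log axis for Asns, Slc7a5, Il2ra, Ifng, Gzmb, Prf1, Tcf7 and Cd8a in each library by time and treatment, points being libraries and black bars the mean ± SD with n = 4. At 48 h Gzmb averaged 5330 CPM with vehicle, 5390 with CB-839, 820 with DON and 1270 in glutamine-free medium.

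Glutamine-free medium against vehicle addressed the loss of the amino acid itself. At 4 h Cth, an enzyme of cysteine synthesis, had risen from 1.12 ± 0.251 to 30.3 ± 4.56 CPM (4.76 ± 0.16, edgeR adjusted p = 6.36e-13), Trib3 by 3.94 ± 0.10, Chac1 by 3.17 ± 0.13 and Sesn2 by 2.65 ± 0.08. Nefh (−2.19 ± 0.09) and the chemokine gene Ccl1 (−2.05 ± 0.32) fell. Ifng (−1.51 ± 0.16), Cd8a (−1.39 ± 0.07) and Gzmc (−1.57 ± 0.15) were lower, and Il2ra (0.41) was higher. In all 6866 genes changed, 2964 up and 3902 down, and 593 and 283 by at least 2-fold; a fit of all 52 libraries gave 2201 up and 4500 down.

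The amino acid response rose in 31 of 35 and fell in 0 at 4 h (32 and 1 adjusted over the list alone, camera adjusted p = 3.6e-26, adjusted p = 0.111 with an estimated correlation). Pck2 was at 2.29 ± 0.09 and Asns at 1.96 ± 0.06. T cell activation genes rose in 15 of 25 and fell in 2 (15 and 2 adjusted over the list alone, camera adjusted p = 4.63e-06, adjusted p = 0.212 with an estimated correlation). Egr1 was at 1.90 ± 0.10 and Nr4a2 at 1.18 ± 0.06. Interferon-stimulated genes rose in 11 of 26 (11 adjusted over the list alone, camera adjusted p = 0.00168, adjusted p = 0.667 with an estimated correlation). Gbp2 was at 1.22 ± 0.16; the B cell share of counts in these libraries ranged widely, at 0.255% ± 0.122 (SD). Cholesterol genes fell in 18 of 22 and rose in 2 (20 and 2 adjusted over the list alone, camera adjusted p = 6.35e-09, adjusted p = 0.341 with an estimated correlation). Oxidative phosphorylation genes fell in 30 of 40 with 1 up (32 and 1 adjusted over the list alone, camera adjusted p = 4.13e-08, adjusted p = 0.382 with an estimated correlation). ER unfolded protein response genes fell in 15 of 18 and rose in 2 (15 and 2 adjusted over the list alone, camera adjusted p = 4.86e-07, adjusted p = 0.212 with an estimated correlation). Pdia4 was at −1.41 but Herpud1 at 1.13 ± 0.05. NRF2 targets fell in 12 of 19 and rose in 3 (12 and 3 adjusted over the list alone, adjusted p = 0.26 with an estimated correlation), the risers including Srxn1 (2.35 ± 0.13) and Hmox1 (1.95).

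More lists were called at 4 h without glutamine with the preset correlation and not with an estimated one. TCA cycle genes fell in 14 of 21 with 1 up (14 and 1 adjusted over the list alone, adjusted p = 0.341 with an estimated correlation). Purine genes fell in 9 of 12 (10 adjusted over the list alone, adjusted p = 0.347 with an estimated correlation). Pyrimidine genes fell in 8 of 14 (9 adjusted over the list alone, adjusted p = 0.212 with an estimated correlation). Glycolysis genes fell in 10 of 20 with 2 up (11 and 3 adjusted over the list alone, adjusted p = 0.382 with an estimated correlation). Cytotoxic granule genes fell in 7 of 13 and rose in 1 (9 and 1 adjusted over the list alone, adjusted p = 0.441 with an estimated correlation). Serine and one-carbon genes rose in 7 of 14 and fell in 3 (7 and 3 adjusted over the list alone, adjusted p = 0.62 with an estimated correlation). Apoptosis regulators rose in 10 of 21 and fell in 4 (10 and 5 adjusted over the list alone, adjusted p = 0.212 with an estimated correlation).

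At 24 h without glutamine the mitotic gene Ube2c fell from 235 ± 15.9 to 6.13 ± 0.935 CPM (−5.25 ± 0.09, edgeR adjusted p = 2.52e-19), the kinase gene Plk1 from 206 ± 26.6 to 4.93 ± 1.07 CPM (−5.38 ± 0.15), and Pif1 fell by 5.62 ± 0.21. Ccnb1-ps, a pseudogene that shares sequence with its parent gene and is therefore uncertain, was at −4.62 ± 0.13. The desaturase genes Scd1 (ENSMUSG00000037071.3, chromosome 19, 44394455 to 44407879) and Fads2 were at −7.11 ± 0.23 and −4.56 ± 0.13. Scd1 fell from 31.8 ± 4.47 to 0.215 ± 0.144 CPM. Among genes with a mean log2 CPM of at least 3 that met the naming rule Aldh1l2 (3.38 ± 0.30), Trat1 (3.34 ± 0.14), Atf5 (3.18 ± 0.13), Zbtb7b (3.17 ± 0.17), Soat2 (3.01 ± 0.23) and Anxa3 (2.93 ± 0.21) had the largest rises. Ifng (−2.67 ± 0.17), Prf1 (−2.66 ± 0.10), Il7r (−2.44 ± 0.25) and Gzmb (−1.23 ± 0.16) were lower, and the glutamine transporter gene Slc1a5 was higher by 1.01 ± 0.07.

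DNA replication and mitosis genes fell in 40 of 41 at 24 h, with a median of −3.21, and rose in 1 (40 and 1 adjusted over the list alone, camera adjusted p = 7.87e-29, adjusted p = 0.159 with an estimated correlation). The amino acid response rose in 33 of 35 and fell in 1 (33 and 1 adjusted over the list alone, camera adjusted p = 1.14e-13, adjusted p = 0.25 with an estimated correlation). The cystine transporter gene Slc7a11 was at 3.34 ± 0.19 and Ddit3 at 2.03 ± 0.12. Cholesterol genes fell in 20 of 22 (20 adjusted over the list alone, camera adjusted p = 7.9e-09, adjusted p = 0.159 with an estimated correlation). Glycolysis genes fell in 19 of 20 with 1 up (19 and 1 adjusted over the list alone, camera adjusted p = 6.06e-08, adjusted p = 0.25 with an estimated correlation). Pyrimidine genes fell in 11 of 14 (11 adjusted over the list alone, camera adjusted p = 3.63e-07, adjusted p = 0.159 with an estimated correlation). Interferon-stimulated genes rose in 21 of 26 and fell in 0 (22 and 0 adjusted over the list alone, camera adjusted p = 1.49e-06, adjusted p = 0.406 with an estimated correlation). Effector differentiation genes fell in 11 of 17 and rose in 2 (11 and 2 adjusted over the list alone, adjusted p = 0.406 with an estimated correlation). The NKG2D gene Klrk1 was at −2.11 ± 0.08. TCA cycle genes fell in 16 of 21 with 3 up (16 and 3 adjusted over the list alone, adjusted p = 0.25 with an estimated correlation). Purine genes fell in 8 of 12 with 1 up (8 and 1 adjusted over the list alone, adjusted p = 0.406 with an estimated correlation). Ribosome biogenesis genes fell in 15 of 32 with 4 up (15 and 4 adjusted over the list alone, adjusted p = 0.798 with an estimated correlation). In all 9582 genes changed, 4888 up and 4694 down, and 1318 and 1142 by at least 2-fold. Higher genes made up 51% of the calls with TMM and 61.4% with library totals alone, which put the median of all genes at 0.127.

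After 48 h without glutamine Scd1 was at −9.20 ± 0.26 and Fads2 at −6.37 ± 0.12. The level of Scd1 was 0.114 ± 0.0383 against 71.3 ± 7.64 CPM. The lactate exporter gene Slc16a3 (−3.88 ± 0.13), Tubb6 (−3.88 ± 0.20), Maats1 (−3.85 ± 0.10) and Prr5 (−3.66 ± 0.18) were also lower. Among genes with a mean log2 CPM of at least 3 that met the naming rule Aldh1l2 (4.48 ± 0.17), Trat1 (4.39 ± 0.20), Atf5 (3.68 ± 0.09), Nupr1 (3.58 ± 0.16), Cth (3.47 ± 0.14) and Slc7a3 (3.43 ± 0.12) had the largest rises, and Asns stood at 409 ± 6.72 against 77.2 ± 5.56 CPM (2.40 ± 0.09, edgeR adjusted p = 4.95e-13). Gzmb was at 1270 ± 260 against 5330 ± 673 CPM (−2.07 ± 0.13), Prf1 at −2.65 ± 0.12, Ifng at −2.14 ± 0.25, Pdcd1 at −1.58 ± 0.07 and Il7r at −1.30 ± 0.10. In all 8777 genes changed, 4528 up and 4249 down, and 1082 and 747 by at least 2-fold; higher genes made up 51.6% of the calls with TMM and 63.5% with library totals alone, which put the median of all genes at 0.123.

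All 22 cholesterol genes fell at 48 h (22 adjusted over the list alone, camera adjusted p = 2.93e-20, adjusted p = 0.000874 with an estimated correlation). Amino acid response genes rose in 33 of 35 and fell in 1 (34 and 1 adjusted over the list alone, camera adjusted p = 2.93e-20, adjusted p = 0.0475 with an estimated correlation). Glycolysis genes fell in 19 of 20 (20 adjusted over the list alone, camera adjusted p = 1.66e-13, adjusted p = 0.0475 with an estimated correlation). Hypoxia response genes fell in 15 of 19 with 3 up (15 and 3 adjusted over the list alone, camera adjusted p = 4.61e-06, adjusted p = 0.0475 with an estimated correlation). DNA replication and mitosis genes fell in 26 of 41 and rose in 3, now with a median of −0.29 (26 and 3 adjusted over the list alone, camera adjusted p = 4.3e-06, adjusted p = 0.0475 with an estimated correlation), and Plk1 was at −0.80 ± 0.05. Ribosome biogenesis genes fell in 26 of 32 (26 adjusted over the list alone, camera adjusted p = 1.1e-08, adjusted p = 0.0791 with an estimated correlation). Pyrimidine genes fell in 10 of 14 (10 adjusted over the list alone, adjusted p = 0.0943 with an estimated correlation). TCA cycle genes fell in 14 of 21 (14 adjusted over the list alone, adjusted p = 0.0522 with an estimated correlation). Purine genes fell in 9 of 12 with 1 up (9 and 1 adjusted over the list alone, adjusted p = 0.26 with an estimated correlation). Oxidative phosphorylation genes fell in 18 of 40 with 1 up (15 and 1 adjusted over the list alone, adjusted p = 0.56 with an estimated correlation).

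More lists were called at 48 h without glutamine with the preset correlation and not with an estimated one. Cytotoxic granule genes fell in 7 of 13 and rose in 2 (8 and 2 adjusted over the list alone, camera adjusted p = 0.0137, adjusted p = 0.391 with an estimated correlation), Crtam being higher at 0.65. CD8 T cell markers fell in 8 of 13 and rose in 1 (8 and 2 adjusted over the list alone, camera adjusted p = 0.0338, adjusted p = 0.397 with an estimated correlation). Thy1 was at −1.01 ± 0.06 and Cd8b1 at −0.52 ± 0.04. Markers of CD4 T cells rose in 4 of 6 and fell in 1 (4 and 1 adjusted over the list alone, camera adjusted p = 0.0338, adjusted p = 0.288 with an estimated correlation): Trat1 stood at 110 ± 23.2 against 5.24 ± 0.454 CPM, while Cd40lg was at −1.09 ± 0.18. The CD4 list took 0.0204% ± 0.0032 (SD) of counts against 0.003% ± 0.0002 (SD) with vehicle. Apoptosis regulators rose in 12 of 21 and fell in 5 (13 and 5 adjusted over the list alone, camera adjusted p = 0.0338, adjusted p = 0.288 with an estimated correlation). The death receptor inhibitor gene Cflar was at 1.02 ± 0.07. ER unfolded protein response genes fell in 13 of 18 and rose in 4 (13 and 4 adjusted over the list alone, camera adjusted p = 0.00127, adjusted p = 0.248 with an estimated correlation).

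**Figure D3:**
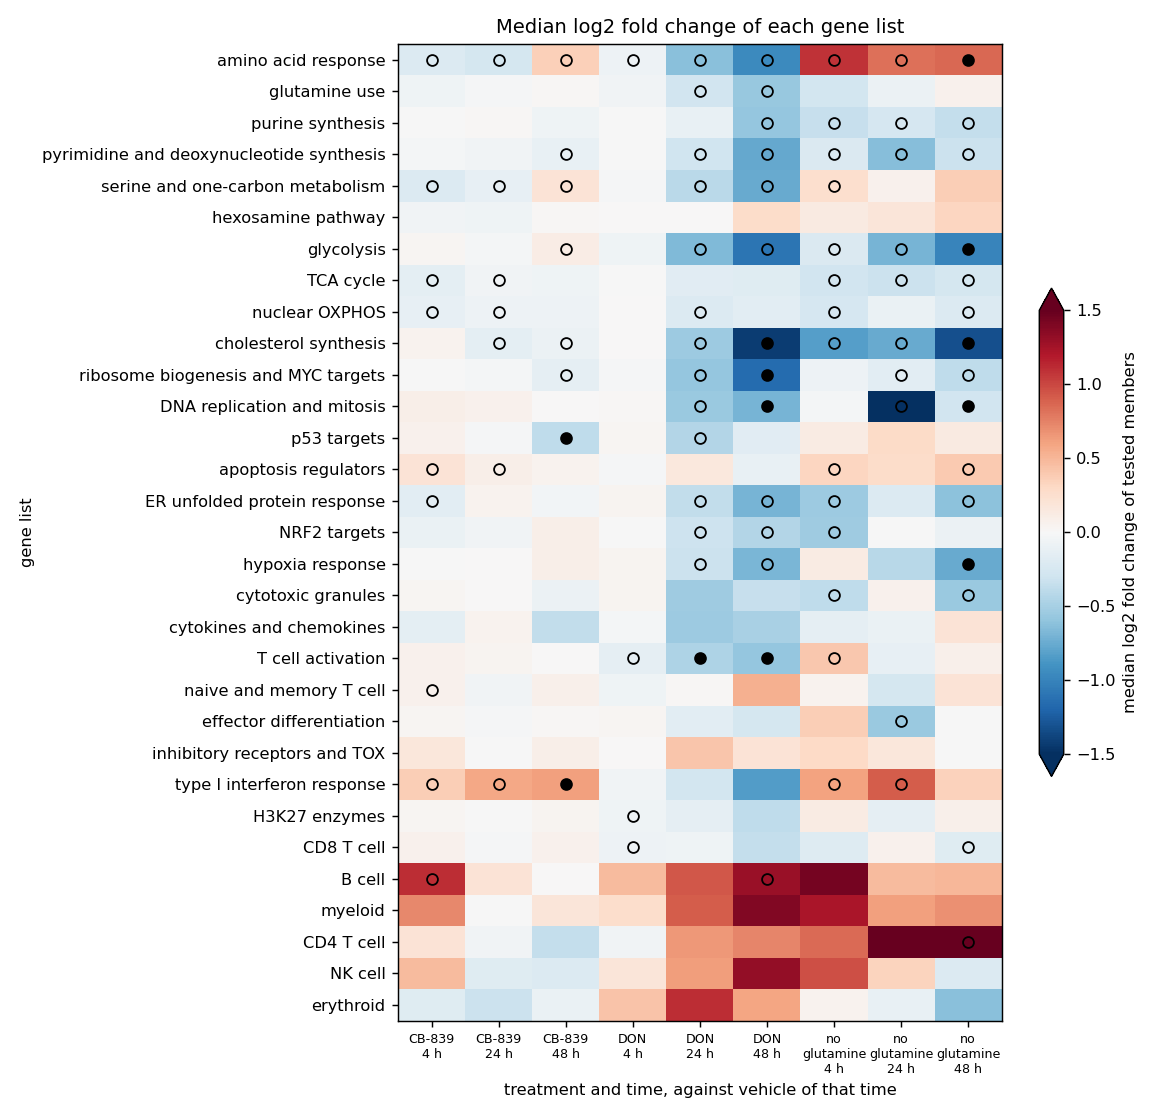
Median log2 fold change against vehicle for 31 gene lists (vertical axis) under each treatment and time (horizontal axis), with the colour scale ending at 1.5 in either direction, open circles marking lists called with a preset correlation of 0.01 and filled circles those also called with an estimated correlation. The amino acid response had a median of 0.36 with CB-839, −0.96 with DON and 0.86 in glutamine-free medium at 48 h.

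Hexosamine, cytokine, inhibitory receptor, myeloid, NK cell and erythroid lists were called in no comparison of a treatment with vehicle in the unblocked fit. Of 8 hexosamine pathway genes 6 rose and 1 fell at 48 h without glutamine (adjusted p = 0.128 in camera). Cytokines and chemokines had 5 up and 11 down of 20 with DON at 24 h (adjusted p = 0.0712 in camera). Inhibitory receptors and TOX had 8 up and 2 down of 17 with DON at 48 h (adjusted p = 0.263 in camera), where Nt5e rose by 2.66 ± 0.18 and Pdcd1 was at −1.35 ± 0.07. Myeloid markers had 2 up of 4 with DON at 48 h (adjusted p = 0.326 in camera), NK cell markers 3 up of 3 (adjusted p = 0.145 in camera), and erythroid markers 2 up of 3 with DON at 24 h (adjusted p = 0.192 in camera). With the replicate letter as a block, cytokines and chemokines (camera adjusted p = 0.0447) and myeloid markers (camera adjusted p = 0.013) were called with CB-839 at 4 h. Genes of the mitochondrial genome had 0 counts in every library and were not tested.

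DON and CB-839 were compared at 1 µM and matched times. At 4 h DON exceeded CB-839 in Gzmc (1.39 ± 0.15) and Nipsnap2 (1.03 ± 0.07) and lay below it in Dnajb13 (−1.65 ± 0.12) and Lipg (−1.12 ± 0.06), with 2922 genes changed (1401 up, 1521 down). The split by direction depended on the fit, with 569 up and 2387 down in a fit of all 52 libraries, 805 and 1315 with no low-count filter and 1970 and 1479 with library totals alone. At 24 h Tbc1d4 (3.69 ± 0.13) and Neat1 (3.50 ± 0.08) were higher with DON, and Hist1h2bj (−3.40 ± 0.20) and Lipg (−2.91 ± 0.13) lower, with 9719 genes changed (4710 up, 5009 down). At 48 h Itgae (4.84 ± 0.16), Lgals3 (4.65 ± 0.15) and Amn1 (4.41 ± 0.13) were higher and Chac1 (−5.18 ± 0.30), Nupr1 (−4.38 ± 0.26), Scd1 (−4.28 ± 0.17) and the interferon-inducible Oas3 (−3.85 ± 0.16) lower, with 11391 changed (5774 up, 5617 down). Higher genes made up 48.5% of these calls at 24 h and 50.7% at 48 h with TMM, and 68.3% and 62.7% with library totals alone.

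By gene list at 48 h, DON lay below CB-839 in 32 of 35 amino acid response genes and above it in 1 (32 and 1 adjusted over the list alone, camera adjusted p = 6.57e-13, adjusted p = 0.0533 with an estimated correlation), and in 16 of 23 interferon-stimulated genes with 1 above (16 and 1 adjusted over the list alone, camera adjusted p = 5.41e-05, adjusted p = 0.0491 with an estimated correlation). Irf7 was at −4.00 ± 0.19 and Parp14 at −2.26. Targets of p53 were higher with DON in 15 of 22 and lower in 3 (15 and 3 adjusted over the list alone, camera adjusted p = 0.00686, adjusted p = 0.162 with an estimated correlation). Ribosome biogenesis genes were lower in 30 of 32 (31 adjusted over the list alone, adjusted p = 0.02 with an estimated correlation). Cholesterol genes were lower in 21 of 22 with 1 higher (21 and 1 adjusted over the list alone, adjusted p = 0.0128 with an estimated correlation). T cell activation genes were lower in 17 of 25 with 1 higher (17 and 1 adjusted over the list alone, adjusted p = 0.0126 with an estimated correlation). Enzymes of H3K27 marks were lower in 10 of 18 and higher in 1 (10 and 1 adjusted over the list alone, camera adjusted p = 0.0498, adjusted p = 0.464 with an estimated correlation). The demethylase gene Kdm6b was at −1.56 ± 0.07 and Ezh1 at 1.03 ± 0.05; with the replicate letter as a block this list had adjusted p = 0.0529. At 24 h ER unfolded protein response genes (14 of 18 lower, 1 higher, 15 and 1 adjusted over the list alone) and T cell activation genes (17 of 25 lower, 1 higher, 17 and 2 adjusted over the list alone) each had adjusted p = 0.038 with an estimated correlation. At 4 h oxidative phosphorylation genes were higher with DON in 11 of 40 (18 adjusted over the list alone, camera adjusted p = 8.47e-07, adjusted p = 0.609 with an estimated correlation). T cell activation genes were lower in 11 of 25 and higher in 2 (12 and 3 adjusted over the list alone, camera adjusted p = 8.96e-05, adjusted p = 0.609 with an estimated correlation).

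Glutamine-free medium was set against each compound. Against CB-839, Cth (5.57 ± 0.17) and Trib3 (4.58 ± 0.10) were higher at 4 h. At 24 h Aldh1l2 (4.72 ± 0.34) was higher and Scd1 (−6.71), Plk1 (−5.47) and Ube2c (−5.22) lower, and at 48 h Trat1 (4.85 ± 0.20) was higher and Scd1 (−8.84), Fads2 (−6.15) and Ak4 (−3.65) lower. The changed genes numbered 5728 at 4 h, 9435 at 24 h and 8250 at 48 h. Of those at 4 h 41% were higher, and 23.7% of the calls in a fit of all 52 libraries. Higher genes made up 50.2% of the calls at 24 h and 52.1% at 48 h with TMM, and 60.3% and 62.7% with library totals alone. At 48 h p53 targets were higher in 17 of 22 and lower in 2 (17 and 2 adjusted over the list alone, camera adjusted p = 8.6e-06, adjusted p = 0.0535 with an estimated correlation). Against DON, Cth (4.91) and Trib3 (4.16) were higher at 4 h. With the replicate block, naive and memory genes were called against DON at 24 h (camera adjusted p = 0.0407, 0.0733 without it). At 24 h Tspan2 (−6.53 ± 0.15), Tbc1d4 (−4.78), Nebl (−4.65) and Scd1 (−4.47) were lower, and at 48 h Nupr1 (7.44 ± 0.23), Chac1 (6.44) and Trib3 (6.02 ± 0.12) were higher and Igfbp7 (−5.48) lower. The changed genes numbered 6600, 9577 and 11102. At 48 h all 35 amino acid response genes were higher than with DON (35 adjusted over the list alone, camera adjusted p = 5.67e-21, adjusted p = 0.0468 with an estimated correlation). T cell activation genes were higher in 18 of 25 with 3 lower (18 and 3 adjusted over the list alone, camera adjusted p = 0.000164, adjusted p = 0.015 with an estimated correlation). Inhibitory receptors and TOX were lower in 11 of 17 with 1 higher (11 and 1 adjusted over the list alone, camera adjusted p = 0.0289, adjusted p = 0.0878 with an estimated correlation).

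Overlaps of changed genes were counted. DON and glutamine-free medium shared 2303 genes up and 2620 down at 24 h, and 1459 moved in opposite directions. Independent lists of those sizes would share 1372.1 and 1404.0. At 48 h the pair shared 2578 up and 2786 down, against 1611.2 and 1512.8, with 1482 opposite. CB-839 and glutamine-free medium shared 677 up and 843 down at 4 h, against 173.4 and 259.0, and 871 up and 650 down at 48 h, against 385.0 and 286.1. CB-839 and DON shared 125 up and 152 down at 24 h, against 112.8 and 120.8, with 305 opposite. At 48 h these were 692 and 644, against 489.3 and 387.7, with 641 opposite. Opposite moves had no expected count, so net agreement was not tested. Fold changes across genes, which are not independent replicates, correlated at r = 0.48, 0.43 and 0.41 between DON and glutamine-free medium at the 3 times, at 0.50, 0.22 and 0.35 between CB-839 and glutamine-free medium, and at 0.21, 0.09 and 0.17 between CB-839 and DON. Because vehicle libraries are shared, simulated unchanged groups gave a mean r of 0.50 to 0.52. The simulation had no pairing by letter, so its covariance may be too large where letters pair samples. The observed covariance minus the simulated one was 0.0729, 0.279 and 0.357 for DON and glutamine-free medium, 0.0554, 0.037 and 0.0831 for CB-839 and glutamine-free medium, and −0.0156, 0.0021 and 0.068 for CB-839 and DON. With the vehicle libraries split between the comparisons, r at 48 h was 0.31 to 0.38, 0.10 to 0.20 and 0.06 to 0.14 for these pairs, and DON and glutamine-free medium shared 2021 to 2282 genes up and 2243 to 2617 down. At 24 h these counts were 1682 to 1786 and 2103 to 2243. For CB-839 and glutamine-free medium the split counts were 287 to 409 up and 358 to 524 down at 4 h, and 331 to 774 up and 154 to 625 down at 48 h. For CB-839 and DON at 48 h they were 242 to 755 and 137 to 931. Divided by the overlap of independent lists of the same split's sizes, these counts gave ratios at 48 h of 1.34 to 1.67 up and 1.59 to 1.95 down for DON and glutamine-free medium. The ratios were 1.65 to 2.75 and 1.45 to 2.37 for CB-839 and glutamine-free medium and 1.01 to 1.49 and 1.2 to 1.63 for CB-839 and DON. At 4 h CB-839 and glutamine-free medium gave 4.44 to 5.55 up and 3.31 to 4.12 down, and at 24 h DON and glutamine-free medium gave 1.57 to 1.8 and 1.79 to 2.01. CB-839 and DON at 24 h gave 0.66 to 0.95 up, and 0.91 to above 1 down.

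H3K27ac, a mark of active promoters and enhancers, was listed at 9681 peaks in vehicle, 6687 in glutamine-free medium, 117 with CB-839 and 33 with DON at 48 h. The lists covered 24.65, 20.21, 0.69 and 0.26 Mb. H3K27me3, the mark placed by Polycomb, had 13556 peaks in vehicle, 12417 with CB-839, 8795 in glutamine-free medium and 3533 with DON. Of the vehicle H3K27ac peaks 55.26% were overlapped by at least 1 base in glutamine-free medium, 0.42% with DON and 131 of 9681 with CB-839. For H3K27me3 the shares were 62.6% with CB-839, 45.12% in glutamine-free medium and 21.76% with DON. Each list came from the authors' comparison of 2 replicates at an irreproducible discovery rate (IDR) of 0.05, so the number of peaks depends on the agreement of the pair and no test between conditions was run. A threshold of IDR 0.02 left 68 vehicle H3K27ac peaks of 9681, and IDR 0.01 left 0.

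Promoters within 1000 bases of a transcription start carried H3K27ac in 7990 of 55364 genes in vehicle, 5465 in glutamine-free medium, 136 with CB-839 and 60 with DON. In the same order H3K27me3 was listed at 5671, 4511, 5843 and 2298 promoters, and both marks at 101, 12, 0 and 0. At the Asns promoter H3K27ac (chromosome 6, 7692141 to 7693392) was listed only without glutamine, and H3K27me3 without glutamine and with CB-839. Il2ra carried a broad H3K27ac peak in vehicle (chromosome 2, 11640104 to 11656281) and in glutamine-free medium (11640710 to 11658091). Gzmb had H3K27ac peaks in vehicle (chromosome 14, 56259150 to 56263180) and glutamine-free medium (56259842 to 56263020), although its transcript was lower in the latter. Ccr9 (chromosome 9, 123672485 to 123683904 in vehicle) carried H3K27me3 in all 4 lists. Of 63 genes chosen at 48 h by the naming rule and panel, an H3K27ac promoter peak was listed for 24 in vehicle, 27 in glutamine-free medium, 1 with CB-839 and 0 with DON.

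Transcripts of marked genes were compared at 48 h. The 6696 tested genes with an H3K27ac promoter peak in vehicle and none with CB-839 had a median log2 fold change of −0.016 against −0.001 in other genes (camera adjusted p = 0.672). With DON the corresponding 6762 genes had a median of −0.088 against 0.071 (camera adjusted p = 0.0608), and in glutamine-free medium 2797 genes had −0.036 against 0.034 (camera adjusted p = 0.457). The 1718 genes with H3K27me3 in vehicle had a median of 0.265 with DON against −0.027 in other genes (camera adjusted p = 0.0608). The 100 genes keeping H3K27ac with CB-839 had a median of 0.06 against −0.008 (camera adjusted p = 0.0698, adjusted p = 0.0288 with an estimated correlation), and at 2500 bases 105 genes gave camera adjusted p = 0.0485. Of the 22 sets tested none passed at 1000 bases with the preset correlation.

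**Figure D4:**
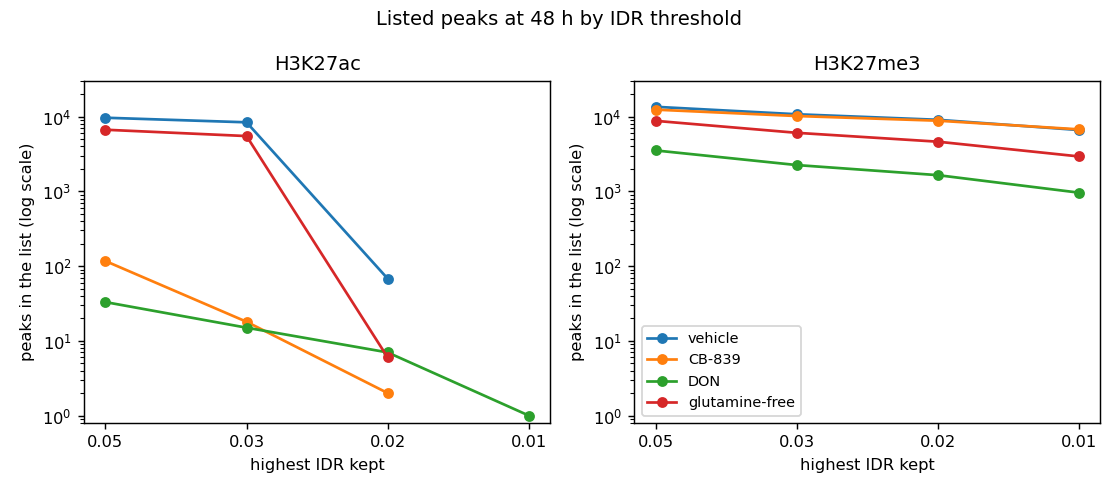
Number of listed peaks (log axis) against the highest IDR kept, from 0.01 to 0.05, for H3K27ac and H3K27me3 in each condition, with lists of 0 peaks not drawn and no replicate lists to give error bars. The vehicle H3K27ac list fell from 8408 peaks at IDR 0.03 to 68 at 0.02, whereas the vehicle H3K27me3 list held 10778 and 9086.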

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

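The tests of the IDR threshold, of transcripts with DON and of Cd4 below were chosen only after the result was seen.

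CB-839 effects that differed between 24 h and 48 h, tested as an interaction, were the amino acid response (median −0.26 and 0.36, difference 0.59, adjusted p = 0.000438 with an estimated correlation), serine and one-carbon genes (−0.12 and 0.20, difference 0.34, adjusted p = 0.047 with an estimated correlation) and p53 targets (−0.02 and −0.38, difference −0.40, adjusted p = 0.00306 with an estimated correlation). Without glutamine, DNA replication and mitosis genes differed by 2.82 between 24 h (−3.21) and 48 h (−0.29, adjusted p = 0.00229 with an estimated correlation). Of 186 such differences 62 were called with the preset correlation and these 4 also with an estimated one; the restriction to the 4 was made after the values were seen.

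The lists of H3K27ac peaks with CB-839 (117) and DON (33) were far shorter than that of vehicle (9681). Of the listed vehicle peaks 0.7% passed an IDR of 0.02, so the lists sit near the limit set by agreement between 2 replicates, and this threshold may account for part of the shortness. Had the mark been lost at vehicle H3K27ac promoters and only their transcripts fallen, their median would lie at least 0.1 below that of other genes. With CB-839 the medians differed by −0.016, which argues against a fall limited to these genes. A fall shared with the other genes would leave no difference between the medians, so the test cannot decide on it. With DON the medians differed by −0.159, but the set was not called (camera adjusted p = 0.0608), so a fall limited to these genes stays open for DON. A change of the mark without a change of transcripts stays open, as does a difference in quality between CUT&RUN samples, since peak calls and signal tracks of single samples were not analysed here.

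The amino acid response was below vehicle at 4 h and 24 h of CB-839 and above it at 48 h with the preset correlation, but not with an estimated one (adjusted p = 0.707, 0.231 and 0.0645). Vehicle library C at 48 h differed from the other 3 by a chi-square of 73.92 to 156.13 per degree of freedom, where those 3 differed by 7.58 to 25.82. Its ribosomal protein share was 6.873% of counts (4.088% to 4.663% in the others), whose Dixon ratio of 0.794 does not set it apart at the 95% limit. Without it 3694 genes changed against 2464, and 27 members were higher at 48 h, which argues against that library as the source of the rise. Under 2 other scalings the lower median was 0.35, which argues against scaling. A delayed response of the cells is a hypothesis that these data do not test further.

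The CD4 T cell list was called higher in glutamine-free medium at 48 h (camera adjusted p = 0.0338, adjusted p = 0.288 with an estimated correlation) and not at 24 h (camera adjusted p = 0.0633), with Trat1 at 110 ± 23.2 against 5.24 ± 0.454 CPM at 48 h. More CD4 T cells would raise Cd4 with the list, but Cd4, below the count filter, had 16 counts over the vehicle libraries and 9 over the glutamine-free ones. Its upper 95% bound of 0.70 lay below 1.36, which is 50% of the median of 2.71 for Trat1, Zbtb7b and Izumo1r. Cd40lg was lower by −1.98 ± 0.13 at 24 h and −1.09 ± 0.18 at 48 h. Induction of these genes in CD8+ T cells is a hypothesis that was not tested.

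Single libraries stood apart from the other 3 of their group in 7 of 104 values tested, where chance marks about 1 in 20, or 5.2. Glutamine-free library B at 4 h had 36.7 M counts (42.12 to 42.67 in the others). CB-839 library B at 48 h had a ribosomal protein share of 4.717% (4.512% to 4.53%). CD8 marker shares were 0.4924% in CB-839 library C (0.5015% to 0.5031%) and 0.4992% in DON library C (0.5123% to 0.5141%) at 48 h. The B cell share was 0.0395% in CB-839 library C at 24 h (0.0381% to 0.0382%), the myeloid share 0.0063% in CB-839 library D at 48 h (0.007% in the others), and the CD4 share 0.006% in vehicle library C at 4 h (0.0054% to 0.0055%).

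Other splits of the 8 libraries of a comparison, 35 in each, were refitted. For 20 of the 21 comparisons only the real split gave as many changed genes. Where letters pair samples only 8 splits part all pairs, so this cannot exclude chance. For DON at 4 h the real split gave 25 genes, another 21 and the reported fit 0, which is weak evidence. For CB-839 at 24 h 2 of the 35 splits gave as many, so chance was not excluded: the real split gave 441 and another 3348, parting libraries A and B from C and D, which points to a structure of the samples. Among the splits that part all 4 pairs the highest other gave 0, and with the replicate block the comparison gave 1840 genes.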

How the results depend on the processing

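The block with only the 8 libraries, and IDR 0.03 and 0.02, were chosen only after seeing the data. Where a count moved, the cause was not tested. CB-839 against vehicle at 4 h (2282 genes) gave 1465 with no count filter, 1518 with all 52 libraries in 1 fit and 4899 with the replicate block among the 8 libraries. DON at 4 h (0 genes) gave 8 with library totals only, 27 by DESeq2, 25 with the 8 libraries and 528 with the block added, but 0 with the block in the shared fit. CB-839 at 24 h (806) gave 1295 by DESeq2, 1840 with the replicate block, 229 with all 52 libraries, 441 with the 8 libraries and 3554 with the block added, and 398 to 789 leaving out 1 library: 485 and 398 without vehicle A and B, 530, 453 and 520 without CB-839 A, C and D. CB-839 at 48 h (2464) gave 1166 with all 52, 1054 with the 8 libraries, 331 with the block added, and 1523 (without CB-839 A) to 3694 leaving out 1 library. The other counts of changed genes stayed within 1.5 times under each alternative run, but not the counts by direction. DON against CB-839 at 4 h (1401 up, 1521 down) gave 569 and 2387 with all 52 libraries and 805 and 1315 with no count filter. Glutamine-free medium against CB-839 at 4 h gave 23.7% up with all 52 libraries, against 41%. At 24 h library totals gave 2813 genes lower with DON than vehicle, against 4866, and 3104 lower than CB-839, against 5009. Without a count filter 13537 and 13259 genes fell at 24 h and 48 h of vehicle against unstimulated cells, against 8338 and 8255. The amino acid response members lower with CB-839 at 24 h (13) numbered 4 to 24 leaving out 1 library and 4 to 29 over the other settings. Of 255 calls in the gene list tests, 29 were made with an estimated correlation and fry made 449, a test that does not compare a list with other genes. Where letters pair the samples, the replicate block ended 2 list calls, naive and memory genes with CB-839 at 4 h (camera adjusted p = 0.0595) and H3K27 enzymes between DON and CB-839 at 48 h (camera adjusted p = 0.0529). It added 5: cytokines (0.0447) and myeloid markers (0.013) with CB-839 at 4 h, glutamine use (0.0391) and naive and memory genes (0.00376) with DON at 4 h, and naive and memory genes between glutamine-free medium and DON at 24 h (0.0407). It changed no other list call in those comparisons. H3K27ac peaks at IDR 0.03, 0.02 and 0.01 numbered 18, 2 and 0 with CB-839 and 15, 7 and 1 with DON. With vehicle they numbered 8408, 68 and 0, and without glutamine 5505, 6 and 0. As covered bases CB-839 had 2.8% and DON 1.1% of vehicle, against 1.2% and 0.3% as peaks. H3K27me3 at 0.01 numbered 6629 with vehicle, 6770 with CB-839 and 2937 without glutamine (4627 at 0.02), and with DON 2252, 1650 and 962 at 0.03, 0.02 and 0.01, where 12.43% of vehicle peaks were overlapped. The set of genes keeping H3K27ac with CB-839 (camera adjusted p = 0.0698) had adjusted p = 0.0288 with an estimated correlation and 0.0485 at 2500 bases. Ezh2 with DON at 48 h (−0.18) was 0 with library totals (edgeR adjusted p = 0.989), which put all genes' median at 0.186. Of the named gene results 2557 were the same and 12 stronger by DESeq2, and 2389 were the same, 5 stronger and 178 weaker with all 52 libraries. Depth of 25.6 to 51 M counts limits genes of low count, and 2 CUT&RUN samples per mark limit the peak lists.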

Other observations

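The genes described here were members of fixed lists or of the fixed panel, and no test of an explanation was added for them.

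The effector differentiation list was not called at 48 h with DON or without glutamine, but single members moved. Prdm1, encoding Blimp-1, was at −4.46 ± 0.29 with DON and −3.47 ± 0.26 without glutamine, while Itgae, the alpha E integrin gene, was at 5.09 ± 0.17 and 2.12 ± 0.18. The ectonucleotidase gene Nt5e was at 2.66 ± 0.18 with DON and Foxp3 at 3.65 ± 0.37, Foxp3 at a low 2.88 against 0.226 CPM and with exons that overlap another gene; the CD4 marker share was 0.0072% ± 0.0004 (SD) with DON against 0.003% ± 0.0002 (SD). Single interferon-stimulated genes were lower with DON at 48 h, with Mx1 at −2.82 ± 0.19 and Parp14 at −1.76 ± 0.08. The pro-apoptotic Bcl2l11 was at 2.37 ± 0.11 with DON at 48 h and at −1.85 without glutamine at 24 h.

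Single genes of transport and of chromatin enzymes are given here without a test of them as groups. Slc1a5, the main glutamine transporter gene, was at −0.71 with DON and 0.87 without glutamine at 48 h. The H3K27 demethylase gene Kdm6b was at −1.16 ± 0.07 with DON and 0.72 without glutamine at 48 h, the methyltransferase gene Ezh1 at 1.29 ± 0.05 with DON, and Acly, which makes acetyl-CoA from citrate, at −0.92 with DON. Ezh2 was at −0.46 ± 0.06 at 24 h without glutamine.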
